A study of Mus musculus with 8 samples.

How the data were processed

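The series held 8 arrays of sorted mouse dendritic cells in 4 groups of 2: cDC1 grown from WT pre-cDC1, cDC2 grown from WT pre-cDC2, cDC2 grown from pre-cDC1 lacking the Irf8 +32 kb enhancer (+32 KO cDC2), and cDC2 grown from Batf3 KO pre-cDC1. Groups were read from the sample titles and descriptions, and the labels give replicate numbers no further meaning. Arrays of the same number correlated at 0.104 to 0.494 after group means were removed, so they may share a batch that the main fit leaves out. Per the labels' protocols, progenitors were sorted from bone marrow by CD117 and CD135 with either a Zbtb46 reporter or CD226 (pre-cDC1) or with CD115 (pre-cDC2), cultured with Flt3L at 100 ng/mL for 5 days, and the resulting cells were sorted again. The labels do not say which gate for pre-cDC1 served which sample, nor whether replicates came from separate mice or cultures. Total RNA was column-extracted, and biotinylated cDNA was made with the Affymetrix WT Pico kit, per the labels' protocols.

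Per the submitters' processing notes, the arrays were processed in Affymetrix Expression Console with RMA; no version or genome build was given. The authors deposited 1 table of 28853 probe sets in the unit intensity: the deposited values are RMA intensities on a linear scale, not log2, with array medians from 55.5 to 57.9. The raw scans were not used. Values were analysed here as log2 of the intensity plus 1.

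Probe sets were named with the annotation table supplied for this platform. It gave exactly 1 gene symbol for 21789 probe sets and several for 1621; 5443 were not listed. The 7064 probe sets without exactly 1 symbol were left out of all gene results and tested on their own. Symbols were checked against a RefSeq table of the assembly GRCm38.p6 through Entrez identifiers: 21698 matched and 0 symbols changed. Of 19938 genes, 999 had more than 1 probe set, and the one with the highest mean was used. An array carries no read depth. Its precision here is given by the fit, where the prior SD was 0.181 log2 units with 2.36 prior degrees of freedom, beside 4 residual degrees of freedom.

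Analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. One limma model with a mean per group was fitted to all 8 arrays (lmFit and eBayes, without trend), which pools the spread of the 4 groups. The 6 pairs of groups were tested, and a gene was called changed at a Benjamini-Hochberg adjusted p < 0.05 over 19938 genes. Every p-value for a gene in the text is from limma, and ± beside a fold change is its SE. With 2 arrays against 2, 33.3% of unchanged genes have groups that do not overlap; observed shares over all genes ran from 27.1% to 50.2%. Genes are named by rules set before the values arrived. These are Batf3 and Irf8 in every group, the 10 largest rises and falls per comparison among genes past the test whose groups do not overlap (predicted genes and small RNAs not named), up to 4 members past the test per list, and any member of the cDC1, cDC2 and transcription factor lists. Genes named in the closing section for other reasons were chosen after the values were seen, as was Ifi202b in the report.

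The 26 gene lists, with 549 of 600 entries measured, were written from general knowledge before the values arrived: cDC1 markers, cDC2 markers, DC fate transcription factors, AP-1 and BATF family, class I antigen presentation and cross-presentation, class II antigen presentation, interferon-stimulated genes, Toll-like receptors, C-type lectins, chemokines and chemokine receptors, cytokines and cytokine receptors, DC maturation, Fc and complement receptors, pDC markers, monocyte and macrophage markers, neutrophil markers, mast cell and basophil markers, lymphocyte markers, erythroid markers, early progenitor markers, cell cycle, immediate early and stress, cholesterol synthesis, glycolysis, retinoid and Notch targets, and apoptosis regulators. Each was tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over 156 tests, and fry was run as well. For calls from the fit of all arrays, camera with an estimated correlation is given beside each call. The 2 forms differ in more than the correlation. Between the WT groups, cDC1 markers had an estimated correlation of -0.026, below the preset, yet their adjusted p went from 6.0e-26 to 0.031. A call lost with an estimated correlation thus cannot be credited to correlation between genes alone. For fits with an array left out, list results are given with the preset correlation alone. Median, mean and test direction differed in sign for 27 of the 156 tests, 0 of them past the threshold. Erythroid markers were measured for 8 genes only, without globins. Counts over a list alone adjust p-values over that list's genes. Lists share genes: 25 of the 32 measured cDC2 markers are also in other lists, and 9 of the 28 C-type lectins are cDC2 markers. Results of lists that share genes are thus not independent.

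The position of each knockout array between WT cDC1 (0) and WT cDC2 (1) was measured in 4 ways, each with 1 array of either WT group choosing the genes (939 to 1201 genes at least 2-fold apart). The summed signed distance of the knockout array from the other WT cDC1 array was divided by that of the other WT cDC2 array, and the 4 values were averaged. The overlap of the knockouts was compared with independent changes and with 100 simulations of unchanged groups. These redrew every array, controls included, around each gene's mean over all arrays, and both knockouts shared the simulated controls. With 2 control arrays, the actual controls could not be split into separate ones for each knockout. Knockouts unchanged from WT cDC1 were also simulated 100 times around the WT cDC1 means, with the uncertainty of those means, to count genes of the WT comparison called by chance. The gene test, the list test and the axis position were tested on simulated data with independent noise, alike in all groups. Other steps, among them the overlap, were not tested in this way. For the gene test, known shifts in 50 randomly drawn genes per size were simulated in the comparisons of a knockout with a WT group. These gave the recovery rates in the report. A shifted gene list was found in 3 of 3 comparisons, with 1 of 153 other tests past the threshold.

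Alternatives planned before the values arrived were a 2-fold requirement, eBayes with trend and robust, leaving out the dimmer genes, cyclic loess, the mean of a gene's probe sets, a fit of the 2 groups compared alone, a replicate block, leaving out each array, 4-fold genes or marker lists for the axis, and an estimated inter-gene correlation. Array weights and log2 without a pseudocount were added after the data were seen. Left out were the raw scans, any reprocessing from them, and pathway databases, none of which were supplied.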

Results

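Dendritic cells that cross-present antigen (cDC1) arise from a committed progenitor, the pre-cDC1, and depend on the transcription factors IRF8 and BATF3. The +32 kb enhancer of Irf8 is the element through which BATF3 sustains Irf8 expression. The series held cDC2 that grew out of pre-cDC1 lacking either Batf3 or this enhancer, beside cDC1 from WT pre-cDC1 and cDC2 from WT pre-cDC2, each sorted after 5 days of culture in Flt3L. The comparisons asked how far the knockout cells had left the cDC1 program, how close they came to WT cDC2, and whether the 2 deletions led to the same cells. Sorted cell type and deletion both differ between the knockout cells and WT cDC1, so differences from WT cDC1 cannot be assigned to the deletions. Progenitor and deletion both differ between the knockout cells and WT cDC2, so differences from WT cDC2 cannot be assigned to the deletions either. Each of the 4 groups had 2 arrays. The labels did not say whether the arrays of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

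Batf3 and Irf8 were examined first in every group. Batf3 averaged 9.89 ± 0.40 (mean ± SD of log2 intensity, n = 2 in this and all other groups) in WT cDC1, 8.80 ± 0.10 in WT cDC2, 9.22 ± 0.64 in +32 KO cDC2 and 7.05 ± 0.06 in Batf3 KO cDC2. It fell against WT cDC1 in Batf3 KO cDC2 (log2 fold change -2.84 ± 0.32, estimate ± SE, adjusted p = 0.018), and in +32 KO cDC2 it lay near WT cDC2 on replicate 1 (8.77) and near WT cDC1 on replicate 2 (9.67). Irf8 averaged 12.42 ± 0.02 in WT cDC1 and 9.12 ± 0.31 in WT cDC2, a log2 difference of 3.30 ± 0.73 that did not pass the test (adjusted p = 0.16). The 2 arrays of +32 KO cDC2 differed widely in Irf8, at 9.70 and 12.04, and those of Batf3 KO cDC2 stood at 10.12 and 11.09. Replicate 2 of +32 KO cDC2 thus lay near WT cDC1 in Irf8. Without it, the log2 fold change against WT cDC1 was -2.72 in the 1 remaining +32 KO array, which does not show a fall for the group. In Batf3 KO cDC2 it was -1.82. Id2, which encodes an inhibitor of E proteins needed for cDC1, averaged 11.14 ± 0.10 in WT cDC1, against 9.79 ± 0.24 in WT cDC2, and did not pass (log2 difference 1.35 ± 0.34, adjusted p = 0.21). Zbtb46, a factor shared by both conventional lineages, lay between 7.94 and 8.59 on every array.

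**Figure D1:**
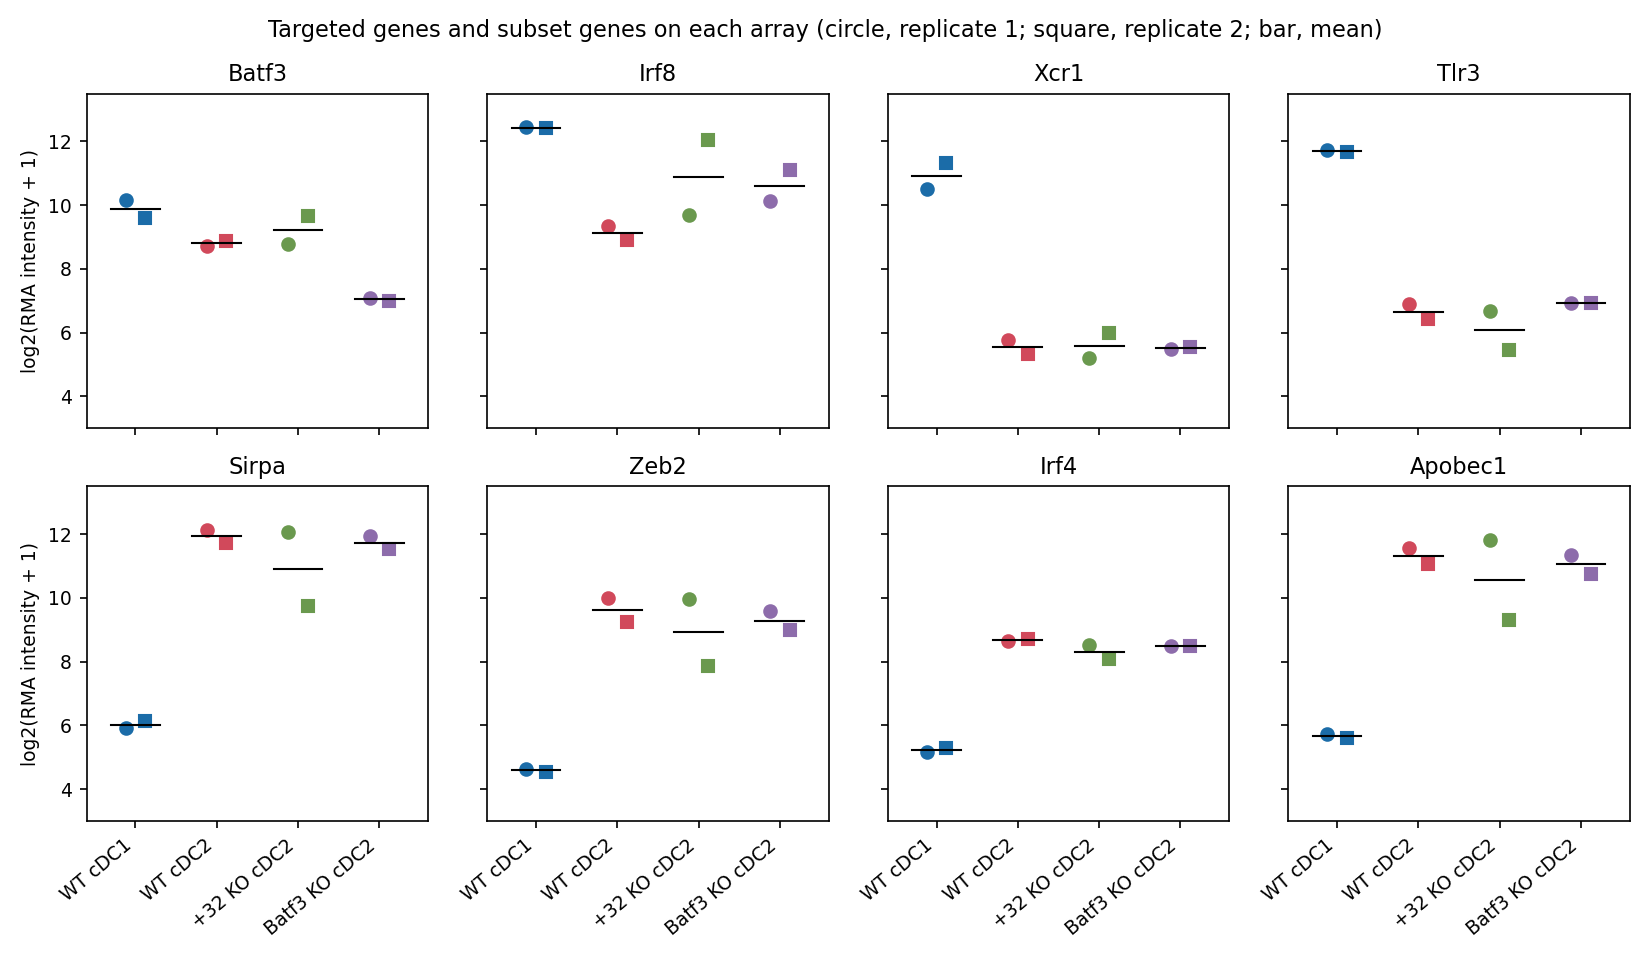
log2 (RMA intensity + 1) of Batf3, Irf8, Xcr1, Tlr3, Sirpa, Zeb2, Irf4 and Apobec1 on each array. Circles are replicate 1, squares are replicate 2, bars are group means of 2 arrays.

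In the WT cells, 112 genes differed between cDC1 and cDC2 (adjusted p < 0.05), 61 of them higher in cDC1 and 51 higher in cDC2. The cDC1 side was led by Ctla2b (log2 fold change 5.52 ± 0.37), P3h2 (5.47 ± 0.40), the chemokine receptor gene Xcr1 (5.35 ± 0.35, adjusted p = 0.0040), Gpr141b (5.18), the sensor of double-stranded RNA Tlr3 (5.05 ± 0.38, adjusted p = 0.0053), Snx22 (4.91 ± 0.24), Gcsam (4.67), Dapk2 (4.32), Rasgrp3 (4.0) and Cldn1 (3.95). The cDC2 side was led by Sirpa (-5.91 ± 0.68, adjusted p = 0.024), Apobec1 (-5.64 ± 0.74), the transcription factor gene Zeb2 (-5.02 ± 0.66), Pla2g7 (-4.96), Tmem176a (-4.63), S100a4 (-4.51), Cd63 (-4.41), Cd72 (-4.34), Tmem176b (-4.33) and Gpnmb (-4.22). Clec9a, whose product binds dead cells, was 5.72 ± 0.82 log2 units higher in cDC1 without passing (adjusted p = 0.054). Of 33 measured transcription factors of dendritic cell fate, Mycl was higher in cDC1 (2.75 ± 0.20) and Irf4 (-3.46 ± 0.18, adjusted p = 0.0020), Zeb2 and Spib (-2.93 ± 0.23) were higher in cDC2. That list did not move as a whole (adjusted p = 0.30). The labels do not give the markers of the final sort, so Sirpa, Xcr1 or other surface genes may themselves have defined the groups.

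Among gene lists, the cDC1 markers were higher in cDC1 with 7 of 30 genes past the test, or 18 when adjusted over the list alone (adjusted p = 6.0e-26 with the preset inter-gene correlation; 0.031 with an estimated one). The cDC2 markers were higher in cDC2, with 6 of 32 genes past the test and 14 over the list alone (adjusted p = 8.65e-17, or 0.45 with an estimated correlation). Interferon-stimulated genes were also higher in cDC2: Ddx58 (-4.01 ± 0.23), Oasl2 (-3.82), Ifit1 (-3.66 ± 0.38) and Oas1a (-2.64) led the 5 of 32 genes past the test (adjusted p for the list = 2.1e-21, or 0.12 with an estimated correlation). Genes of the DC maturation program leaned to cDC2 with a median of -1.30 and Anxa3 alone past the test (adjusted p = 3.05e-09, or 0.51 with an estimated correlation). Cell cycle genes leaned to cDC1 with a median of 1.37. This was 0.91 without WT cDC2 replicate 1 and 1.84 without replicate 2, as the WT cDC2 arrays had list means of 7.19 and 8.12. None of 40 passed over all genes and 30 over the list alone (adjusted p = 3.0e-24, or 0.45 with an estimated correlation). C-type lectins leaned to cDC2 (median -2.36, Clec2i past the test, adjusted p = 1.0e-06, or 0.49 with an estimated correlation), as did Fc and complement receptors (median -1.21, adjusted p = 7.1e-05, or 0.45), class II presentation genes (H2-Eb2 and Lgmn past the test, adjusted p = 1.35e-04, or 0.57) and monocyte and macrophage markers (median -1.16, adjusted p = 2.0e-06, or 0.45). Smaller leanings to cDC2 were found for chemokines and their receptors (Ccl5 and Cxcr4 higher in cDC2, Xcr1 in cDC1; adjusted p = 0.0084, or 0.45 with an estimated correlation), cytokines and their receptors (Il7r higher in cDC2; adjusted p = 0.0051, or 0.335) and pDC markers (Spib; adjusted p = 0.036, or 0.45). Class I and cross-presentation genes leaned to cDC1 (median 0.32, adjusted p = 0.025, or 0.45 with an estimated correlation). Single arrays decided 3 of these calls, which ended without WT cDC1 replicate 1 (chemokines, adjusted p = 0.33, and pDC markers, 0.054), WT cDC1 replicate 2 (pDC markers, 0.12, and class I genes, 0.40), WT cDC2 replicate 1 (class I genes, 0.064) or WT cDC2 replicate 2 (pDC markers, 0.10). The count of 112 became 31 and 34 without WT cDC1 replicates 1 and 2, 17 and 42 without WT cDC2 replicates 1 and 2, 712 without either +32 KO array and 41 without either Batf3 KO array. It was 508 when only the WT arrays were fitted.

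In +32 KO cDC2, 395 genes changed against WT cDC1, 105 higher and 290 lower. The cDC1 genes fell, led by Tlr3 (log2 fold change -5.64 ± 0.38, adjusted p = 0.0038), Clec9a (-5.34 ± 0.82, adjusted p = 0.038), Xcr1 (-5.32 ± 0.35, adjusted p = 0.0038), Ctla2b (-5.14), P3h2 (-5.12), Snx22 (-5.08 ± 0.24), Gpr141b (-4.92), Ifi205 (-4.81), Gcsam (-4.52) and Septin3 (-4.44). The rises were led by Apobec1 (4.88 ± 0.74), Rgs1 (4.88), Sirpa (4.88 ± 0.68, adjusted p = 0.032), Socs2 (4.88), the interleukin-7 receptor gene Il7r (4.64 ± 0.30), Pla2g7 (4.61), Anxa3 (4.55), Cd63 (4.43), Tmem176a (4.39) and Nrp2 (4.37). Irf4 (3.07 ± 0.18, adjusted p = 0.0028), Zeb2 (4.33 ± 0.66) and Spib (2.44 ± 0.23) rose and Mycl fell (-3.02 ± 0.20).

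As lists, cDC1 markers fell in +32 KO cDC2 (14 of 30 genes past the test, adjusted p = 8.65e-17, or 0.031 with an estimated correlation) and cDC2 markers rose (6 of 32, with Fcrla falling; adjusted p = 4.9e-04, or 0.57 with an estimated correlation). The rise of the cDC2 markers as a list was carried by replicate 1, where their mean was 9.02, beside 9.21 and 8.84 in WT cDC2. On replicate 2 it was 6.63, beside 6.64 and 6.50 in WT cDC1, and without replicate 1 the list did not pass (median 0.205, adjusted p = 0.70). Cell cycle genes fell, with 22 of 40 past the test over all genes and 36 over the list alone (adjusted p = 1.0e-28, or 0.45 with an estimated correlation). Plk1 (-4.20 ± 0.59, adjusted p = 0.032), Ccna2 (-3.89), Mki67 (-3.89) and Kif11 (-3.72) led. Interferon-stimulated genes rose (6 of 32 genes past the test, among them Ifit1 at 3.98 ± 0.38 and Ddx58 at 3.75 ± 0.23; adjusted p = 8.9e-10, or 0.335 with an estimated correlation). DC maturation genes rose, with 5 of 25 past the test led by Socs2, Anxa3, Samsn1 (3.83) and the chemokine receptor gene Ccr7 (3.54 ± 0.50, adjusted p = 0.033) (adjusted p = 1.3e-10, or 0.51 with an estimated correlation). Much of this rise came from replicate 2: the list means were 8.798 and 10.755 on replicates 1 and 2, beside 7.164 and 7.608 in WT cDC1. The median of 2.299 became 1.178 without replicate 2. Chemokines and their receptors (Ccl5 and Ccr7 among 3 higher, Xcr1 and Ccr9 lower; adjusted p = 0.034, or 0.45 with an estimated correlation) and cytokines and their receptors (Il7r; adjusted p = 0.033, or 0.45) leaned higher, and class I and cross-presentation genes leaned lower (Rab43 and Psmb9; adjusted p = 0.025, or 0.45). None of these 3 lists passed without replicate 1 of +32 KO cDC2 (adjusted p = 0.77, 0.32 and 0.13). The first 2 also ended without WT cDC1 replicate 1 (adjusted p = 0.26 and 0.066), and class I genes without WT cDC1 replicate 2 (0.26). On simulated data for this comparison, the test found 34%, 90%, 96% and 100% of genes shifted by 1, 2, 3 and 4 log2 units among 19938 genes, and 8 of 168 calls were false. Without +32 KO replicate 2, which stood apart from all other arrays, 543 genes changed, 262 higher and 281 lower, 276 of them among the 395; Clec9a (-4.51, adjusted p = 0.061), Ifi205 (-3.68, adjusted p = 0.055), Ccna2, Ccr9 and Mki67 no longer passed. In that fit, with 1 array left in +32 KO cDC2, medians were 2.24 for C-type lectins, 1.78 for Fc and complement receptors and 1.31 for monocyte and macrophage markers. They were 0.31 for class II genes and 0.70 for Toll-like receptors. With all arrays none of these lists passed, with the preset or an estimated correlation. The count became 6929 without +32 KO replicate 1, 35 and 39 without WT cDC1 replicates 1 and 2, 232 without either WT cDC2 array, 49 without either Batf3 KO array and 0 when only the 4 arrays compared were fitted.

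In Batf3 KO cDC2, 379 genes changed against WT cDC1, 147 higher and 232 lower. The genes that fell were again those of cDC1: Clec9a (log2 fold change -5.58 ± 0.82, adjusted p = 0.034), Xcr1 (-5.39 ± 0.35, adjusted p = 0.0031), Gpr141b (-5.08), Ctla2b (-5.01), Snx22 (-5.00 ± 0.24), P3h2 (-4.83), Tlr3 (-4.78 ± 0.38, adjusted p = 0.0067), Rasgrp3 (-4.71), Gcsam (-4.57) and Dapk2 (-4.33). Pla2g7 (5.90), Sirpa (5.72 ± 0.68, adjusted p = 0.021), Apobec1 (5.37 ± 0.74), Anxa3 (5.36), Gpnmb (5.27), Capg (5.11), Papss2 (5.01), Cd63 (4.81), Tmem176a (4.71) and Il7r (4.70 ± 0.30) rose most. Irf4 (3.27 ± 0.18, adjusted p = 0.0017), Zeb2 (4.70 ± 0.66) and Spib (3.19 ± 0.23) rose, Mycl fell (-3.11 ± 0.20), and in the AP-1 and BATF family Fosl2 rose (2.14) while Batf3 fell. That list of 14 genes did not move as a whole (adjusted p = 0.65).

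The lists, some of which share genes, repeated this pattern in Batf3 KO cDC2. Cell cycle genes fell (17 of 40 past the test over all genes and 37 over the list alone; adjusted p = 1.0e-31, or 0.45 with an estimated correlation), with Plk1 (-4.22 ± 0.59), Ccna2 (-3.89), Kif11 (-3.82) and Top2a (-3.44) in the lead. The cDC1 markers fell (12 of 30; adjusted p = 9.6e-18, or 0.031 with an estimated correlation) and the cDC2 markers rose (6 of 32, with Fcrla falling; adjusted p = 7.7e-12, or 0.45). DC maturation genes rose with Anxa3, Socs2 (4.69), Ccr7 (3.93 ± 0.50) and Tmem123 (2.23) past the test (adjusted p = 8.65e-17, or 0.45 with an estimated correlation). Interferon-stimulated genes rose (Ddx58 3.29 ± 0.23, Oasl2 3.02, Ifit1 2.90 ± 0.38; 6 of 32 genes; adjusted p = 2.2e-08, or 0.335 with an estimated correlation). Chemokines and their receptors rose (Ccr7, Ccl5 and Cxcr4 among 4 higher, Xcr1 lower; adjusted p = 6.6e-04, or 0.45 with an estimated correlation), as did cytokines and their receptors (adjusted p = 8.2e-05, or 0.24). C-type lectins (Clec2i 3.13; adjusted p = 2.75e-05, or 0.51 with an estimated correlation), monocyte and macrophage markers (adjusted p = 8.2e-05, or 0.51), class II presentation genes (H2-Eb2 3.13, Lgmn 2.49; adjusted p = 0.0038, or 0.64) and Fc and complement receptors (adjusted p = 0.013, or 0.51, and 0.23 without Batf3 KO replicate 1) leaned higher. On simulated data for this comparison, 42%, 84%, 98% and 100% of genes shifted by 1, 2, 3 and 4 log2 units were found among 19938 genes, and 9 of 171 calls were false. The count of 379 became 1642 without either +32 KO array, 31 and 44 without WT cDC1 replicates 1 and 2, 34 and 21 without Batf3 KO replicates 1 and 2, and 1253 when only the 4 arrays compared were fitted.

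Against WT cDC2, no single gene passed in either knockout. For +32 KO cDC2, limma gave 0 genes past the threshold and 700 at an unadjusted p < 0.05. For Batf3 KO cDC2 it gave 0 and 492, where 997 of 19938 genes would be below 0.05 by chance. The unadjusted counts depended on single arrays and on the fit, so they do not measure closeness to WT cDC2. For +32 KO cDC2, leaving out 1 array gave from 173 (without WT cDC2 replicate 2) to 8707 (without +32 KO replicate 1), with 395 without +32 KO replicate 2. Fitting only the 4 arrays compared gave 155. For Batf3 KO cDC2, leaving out 1 array gave from 151 (without Batf3 KO replicate 2) to 1553 (without either +32 KO array). Fitting only the 4 arrays compared gave 1317. Of the 61 genes higher in WT cDC1, 60 were lower in +32 KO cDC2 than in WT cDC1 and 57 in Batf3 KO cDC2. Of the 51 genes higher in WT cDC2, 47 and 48 were higher. These counts share the WT cDC1 arrays that chose the genes. Knockouts simulated as unchanged from WT cDC1 gave 0 such genes in each of 100 simulations. The knockout cells were taken as cDC2, so these counts may follow from the sort, and the simulation does not test the deletions. Ifi202b came closest in Batf3 KO cDC2 (log2 fold change 2.40 ± 0.21, adjusted p = 0.37). It passed without either +32 KO array (adjusted p = 0.022), where it was the 1 gene past the test. Simulated shifts of 1, 2, 3 and 4 log2 units were found at rates of 40%, 88%, 94% and 96% for +32 KO cDC2 (12 of 171 calls false). For Batf3 KO cDC2 the rates were 38%, 88%, 98% and 96% (10 of 170 calls false). Most shifts of 2-fold would thus have been missed even there. These simulations drew genes at random and gave them independent noise. On the arrays, 749 genes in +32 KO cDC2 and 237 in Batf3 KO cDC2 lay at least 2-fold from WT cDC2, with 0 called. The rates therefore do not show that larger differences were absent.

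Lists did separate the knockouts from WT cDC2 with the preset correlation. The knockout cells grew from pre-cDC1 and WT cDC2 from pre-cDC2, so progenitor and deletion cannot be told apart here. In Batf3 KO cDC2, cell cycle genes were lower (median -0.77, adjusted p = 4.55e-23, or 0.45 with an estimated correlation), interferon-stimulated genes were lower (median -0.46, adjusted p = 4.1e-09, or 0.335), and all 25 DC maturation genes had estimates above 0 (median 1.14, adjusted p = 8.3e-14, or 0.45). The array means of the DC maturation genes were 9.55 and 10.38 in Batf3 KO cDC2, against 8.57 and 9.11 in WT cDC2. Chemokines and their receptors (adjusted p = 0.0063, or 0.45 with an estimated correlation, and 0.19 without Batf3 KO replicate 1) and cytokines and their receptors (adjusted p = 0.0043, or 0.335) were higher by medians of 0.06 and 0.15. In +32 KO cDC2, cell cycle genes were lower as well (median -0.90, adjusted p = 1.35e-17, or 0.45 with an estimated correlation) and stayed so without replicate 2 (median -0.76). Without WT cDC2 replicate 2 the medians shrank to -0.42 in +32 KO cDC2 (adjusted p = 1.55e-09) and -0.34 in Batf3 KO cDC2 (adjusted p = 1.84e-09). The cDC2 markers (median -0.97, adjusted p = 3.2e-06, or 0.51 with an estimated correlation), class II presentation genes (-0.56, adjusted p = 1.0e-04, or 0.57), Toll-like receptors (-0.91, adjusted p = 0.0051, or 0.64), C-type lectins (-1.17, adjusted p = 0.0040, or 0.64), Fc and complement receptors (-1.20, adjusted p = 0.0094, or 0.51) and monocyte and macrophage markers (-0.45, adjusted p = 0.012, or 0.64) were lower and DC maturation genes were higher (0.98, adjusted p = 8.2e-05, or 0.64). These 7 calls rested on replicate 2 of +32 KO cDC2. Without it the cDC2 markers stood at 0.06, class II genes at 0.01, Toll-like receptors at 0.19, C-type lectins at 0.28, Fc and complement receptors at 0.14, monocyte and macrophage markers at 0.18 and DC maturation genes at -0.02, none past the test. In that fit, with 1 array left in +32 KO cDC2, 5 other lists leaned higher by small medians. These were chemokines and their receptors (0.04), immediate early and stress genes (0.23), retinoid and Notch targets (0.14), cholesterol synthesis genes (0.13) and the AP-1 and BATF family (0.18). With all arrays none of these 5 passed, with the preset or an estimated correlation. Without WT cDC2 replicate 1, Toll-like receptors (adjusted p = 0.087), C-type lectins (0.24), Fc and complement receptors (0.076) and monocyte and macrophage markers (0.88) did not pass either. Without replicate 1 of +32 KO cDC2, 5699 single genes differed from WT cDC2 in this lone array.

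**Figure D2:**
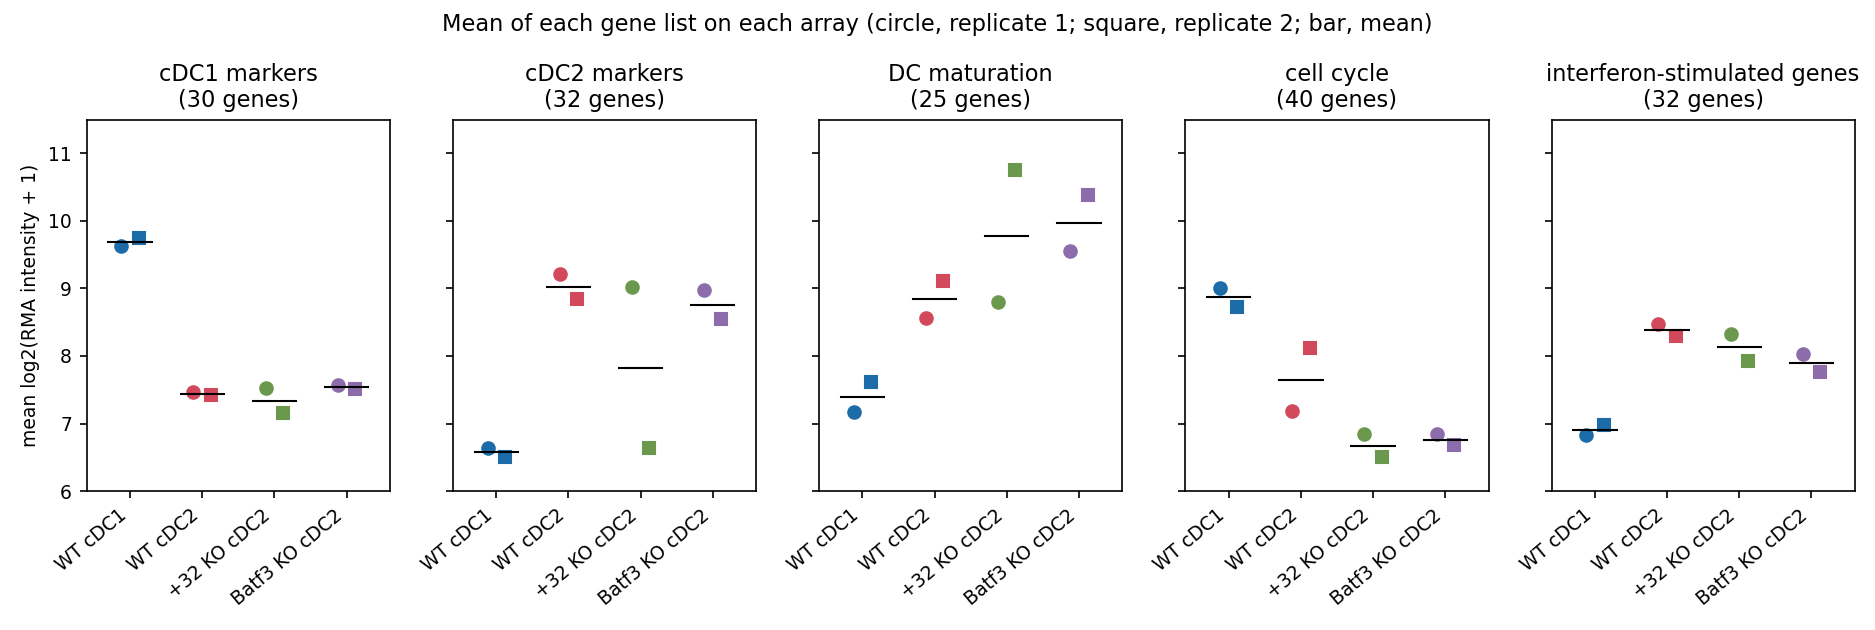
Mean log2 (RMA intensity + 1) of the cDC1 marker, cDC2 marker, DC maturation, cell cycle and interferon-stimulated gene lists on each array. Circles are replicate 1, squares are replicate 2, bars are group means of 2 arrays.

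Many of the genes that changed against WT cDC1 did so in both knockouts: 89 were higher and 198 lower in both, 287 in all, among them Xcr1, Tlr3, Sirpa and Irf4. A further 108 passed only in +32 KO cDC2 and 92 only in Batf3 KO cDC2, and none changed in opposite directions. The sorted cell type differs along with the deletion in these comparisons. Independent changes would share 0.774 and 3.37 genes. In simulations of unchanged groups, all arrays were redrawn, WT cDC1 included, and both knockouts shared the simulated controls. There the knockouts shared a mean of 0.02 genes, at most 1 in 100 simulations. The fold changes of all genes correlated at r = 0.84, against 0.50 for simulated unchanged groups, with covariances of 0.334 and 0.045. The simulated values already hold the effect of shared controls, for the simulated spread. Error in the actual WT cDC1 arrays beyond that spread may still add to the excess. Of the 287 genes, 102 also differed between WT cDC1 and WT cDC2 in the same direction. The 287 became 27 and 36 without WT cDC1 replicates 1 and 2, 1190 and 521 without +32 KO replicates 1 and 2, and 28 and 21 without Batf3 KO replicates 1 and 2. Against WT cDC2 the knockouts shared 0 genes, and fold changes correlated at r = 0.57, against 0.50 for simulated unchanged groups.

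On an axis from WT cDC1 at 0 to WT cDC2 at 1, built from genes at least 2-fold apart between the WT groups, Batf3 KO cDC2 stood at 1.15 and 1.14 and +32 KO cDC2 at 1.16 and 0.869. In simulated data, arrays placed at 0.25 were found at 0.242 and 0.263, and arrays placed at 0.8 at 0.793 and 0.799. When the cDC1 and cDC2 markers alone made the axis, Batf3 KO cDC2 stood at a mean of 1.02 and the +32 KO arrays at 1.02 and 0.732.

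Compared with each other, the knockouts gave 0 genes past the threshold in limma and 771 at an unadjusted p < 0.05. The latter ran from 250 (without Batf3 KO replicate 2) to 7936 (without +32 KO replicate 1) when 1 array was left out, and was 195 when only the 4 arrays compared were fitted. Ifi202b came closest (log2 fold change -1.99 ± 0.21 in +32 KO cDC2 against Batf3 KO cDC2, adjusted p = 0.73), and Batf3, the gene deleted in the latter cells, stood 2.17 ± 0.32 higher in +32 KO cDC2 (adjusted p = 0.79). Without replicate 1 of +32 KO cDC2, 4368 genes differed. Lists that differed between the knockouts are described in the closing section.

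**Figure D3:**
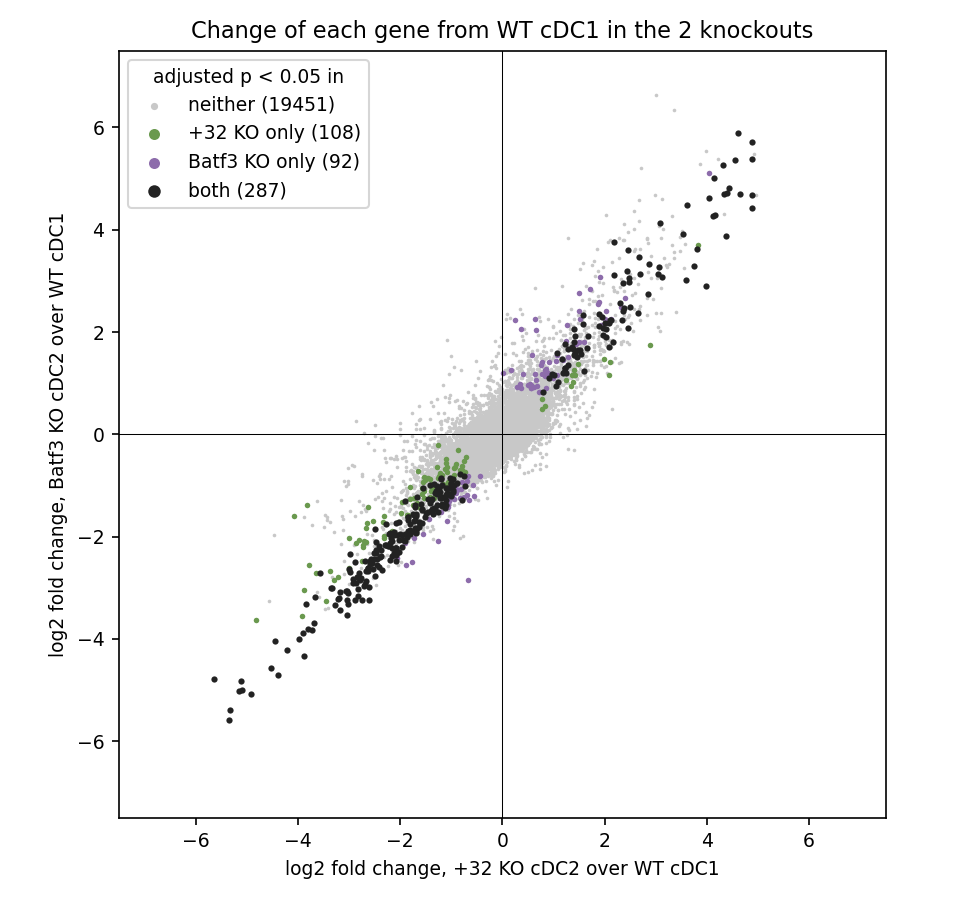
log2 fold change against WT cDC1 of each gene in +32 KO cDC2 (x) and Batf3 KO cDC2 (y). Colours mark genes changed in both (287), in +32 KO cDC2 only (108), in Batf3 KO cDC2 only (92) or in neither (19451).

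Genes of other lineages were examined in the WT groups as a check on the sorts, which cannot show cells common to both groups. Monocyte and macrophage markers leaned to WT cDC2 (median -1.16, camera adjusted p = 2.0e-06, or 0.45 with an estimated correlation). So did pDC markers (camera adjusted p = 0.036, or 0.45), as given above. Neutrophil markers (adjusted p = 0.41), mast cell and basophil markers (adjusted p = 0.90), lymphocyte markers (adjusted p = 0.49), the 8 measured erythroid markers (adjusted p = 0.35) and early progenitor markers (adjusted p = 0.40) did not differ as lists between WT cDC1 and WT cDC2. The exception among early progenitor genes was Cd226, which encodes a surface protein used in the pre-cDC1 gate. It was higher in WT cDC1 (log2 fold change 3.62) and fell in +32 KO cDC2 (-3.99) and Batf3 KO cDC2 (-4.01). Toll-like receptors did not move as a list between the WT groups (adjusted p = 0.40). Tlr3 and Tlr12 (2.79) were higher in cDC1 while the median of all 13 lay at -0.55.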

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

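All explanations weighed in this part were tested after the result was seen.

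There were 9 gene lists that differed between the knockouts with the preset inter-gene correlation. In +32 KO cDC2, against Batf3 KO cDC2, the medians were lower for cDC2 markers (-0.835, adjusted p = 2.8e-05, or 0.51 with an estimated correlation), Toll-like receptors (-0.86, adjusted p = 0.013, or 0.65), C-type lectins (-0.717, adjusted p = 0.0025, or 0.63), class II presentation genes (-0.514, adjusted p = 3.0e-05, or 0.52), monocyte and macrophage markers (-0.374, adjusted p = 0.015, or 0.64), glycolysis genes (-0.371, adjusted p = 0.0012, or 0.51) and cholesterol synthesis genes (-0.316, adjusted p = 5.6e-04, or 0.51). They were higher for interferon-stimulated genes (0.311, adjusted p = 0.0063, or 0.45 with an estimated correlation) and lymphocyte markers (0.166, adjusted p = 0.037, or 0.64). Without replicate 2 of +32 KO cDC2, only the interferon-stimulated genes kept the difference (median 0.412, adjusted p = 8.2e-09), and they lost it without replicate 1 (adjusted p = 0.82) or without Batf3 KO replicate 2 (0.24). Without +32 KO replicate 2, Toll-like receptors leaned in the opposite direction (median 0.361), with a lone array left in +32 KO cDC2. Other medians in that fit were 0.311 for Fc and complement receptors and -1.12 for DC maturation. They were -0.325 for cytokines and their receptors and -0.141 for class I and cross-presentation genes. With all arrays none of these other lists passed, with the preset or an estimated correlation. For DC maturation the median was then -0.156 (adjusted p = 0.11, or 0.82 with an estimated correlation). Without Batf3 KO replicate 1, Toll-like receptors (adjusted p = 0.49), C-type lectins (0.18), monocyte and macrophage markers (0.13) and lymphocyte markers (0.59) did not pass.

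Replicate 2 of +32 KO cDC2 stood apart from the 7 other arrays: it correlated with them at 0.902 to 0.947, against 0.95 to 0.996 among themselves, and 235 genes lay at least 2-fold above and 769 at least 2-fold below every other array. Tnfsf4, Il23r, Cxcr5, Ido1 and Cd80 were among the high genes and Dpep2, Lyz2, Myo1f, Wdfy4 and H2-Ob among the low ones. The range of this array was compressed (interquartile range 2.55 log2 units, against 2.99 to 3.14). After a straight line was removed, DC maturation genes stayed at a median of 2.02, above all 10000 matched random lists. Linear compression thus did not account for the rise of these genes. The random lists drew genes independently, while these genes varied together (estimated correlation 0.703), so that comparison is too favourable. After the same line, medians over all lists ran from -2.27 (Fc and complement receptors) up to that of DC maturation. C-type lectins stayed at -2.23 and cDC2 markers at -1.28, so removing the line did not remove the fall of these lists. Whether compression explains the low correlations or the 769 low genes as a set was not tested. The lists of 6 other cell types stood at most a median of 0.363 above the other cDC2 arrays, but the means of the mast cell and lymphocyte lists (6.13 and 5.02) were the highest of all arrays. Il6 (4.91 log2 units above the other cDC2 arrays), Kit (1.77), Lcn2 (1.52) and Tcf4 (1.14) stood out. Of these, Il6 and Kit are also in the list of cytokines and their receptors, and Tcf4 is in that of transcription factors. Membership in a further list does not tell which cells expressed these genes. A small share of other cells, or of types not listed, was not excluded. Replicate 1 lay at -0.039 from the mean of the WT cDC2 arrays on the DC maturation list, within their range, which the deletion alone would not predict, and what set replicate 2 apart was left open.

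Probe sets without exactly 1 gene name carried signal that the gene results do not use: of 7064, 3 passed between WT cDC1 and WT cDC2, 4 between +32 KO cDC2 and WT cDC1, 8 between Batf3 KO cDC2 and WT cDC1, and 1 each between Batf3 KO cDC2 and WT cDC2 and between the knockouts. The last 2 are the same probe set, 10468877, singled out after its values were seen. Its intensity was 732 and 730 in Batf3 KO cDC2 and 22.3 to 30.2 on the other arrays (log2 fold change 4.70 ± 0.14 against WT cDC2, adjusted p = 3.8e-05). Probe sets 10359870 (2.61) and 10604633 (2.81) were higher in WT cDC1 than in WT cDC2, and 10496592 rose against WT cDC1 in +32 KO cDC2 (4.30) and Batf3 KO cDC2 (4.63).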

How the results depend on the processing

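Of 194 results for named genes, 135 of them past the test, 0 were counted as reversed under any alternative, and no called gene changed sign. This was largely fixed in advance. A reversal was counted only where a gene passed in the main or the alternative fit. Every called gene had groups that do not overlap, so leaving out 1 array could not change its sign. Only cyclic loess and the mean of a gene's probe sets could have done so. Counts of changed genes stayed within 1.5 times of 112 (WT cDC1 against WT cDC2), 395 (+32 KO cDC2 against WT cDC1) and 379 (Batf3 KO cDC2 against WT cDC1) with a 2-fold requirement, trend and robust, cyclic loess, mean probe sets, no pseudocount and without dim genes. Fitting the 2 groups alone gave 508, 0 and 1253. Array weights, chosen after seeing the data, gave 1182, 28 and 1593, with 1 gene (Ifi202b) for Batf3 KO cDC2 against WT cDC2. Both +32 KO arrays were weighted 0.24, against 1.19 to 1.94 for the other arrays. The main fit pools the spread of all 4 groups, and both comparisons without +32 KO cDC2 gained calls in these 2 fits. The +32 KO arrays thus widened the pooled spread behind the counts of 112 and 379. Leaving out 1 array gave 17 to 712, 35 to 6929 and 21 to 1642 for these comparisons, 0 to 5699 and 0 to 1 for +32 KO and Batf3 KO cDC2 against WT cDC2, 0 to 4368 between the knockouts, and overlaps of 21 to 1190 against WT cDC1 and 0 to 1 against WT cDC2. The array left in its group alone is then assumed to vary as the others do. Without dim genes, 36 genes were higher and 49 lower in WT cDC1, against 61 and 51. The Batf3 KO cDC2 position of 1.14 became 1.10 with 4-fold genes and 1.02 with the marker lists. With an estimated correlation, 3 of 60 list results stayed past the test, all of them the cDC1 markers. As given above, this loss cannot be credited to correlation between genes alone. With cyclic loess 52 stayed. Without +32 KO replicate 2, 13 list tests for +32 KO cDC2 reversed in direction, and leaving out 1 array at a time gave these ranges of medians, each highest without that replicate. Against WT cDC2 they were cDC2 markers -1.987 to 0.058, class II genes -1.139 to 0.011, Toll-like receptors -2.235 to 0.192, C-type lectins -2.478 to 0.276, Fc and complement receptors -2.635 to 0.136, monocyte markers -1.207 to 0.178 and glycolysis -0.472 to -0.003. Against Batf3 KO cDC2 they were cDC2 markers -1.995 to 0.290, class II genes -1.073 to 0.144, Toll-like receptors -2.301 to 0.361, C-type lectins -2.531 to 0.191, monocyte markers -0.866 to 0.222 and glycolysis -0.598 to 0.073. A replicate block gave 125, 486, 483, 0, 0 and 0 genes and kept all 60 list results and 190 of the 194 for named genes. Arrays of the same number correlated at 0.104 to 0.494 after group means were removed. The labels give them only a shared number, and a shared batch was not excluded. Signal over background was not given for these arrays, so dim genes cannot be called absent.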

Other observations

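The tests of explanations in this part were chosen after the result was seen.

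Genes of metabolism were compared as well. Fdps, which encodes farnesyl diphosphate synthase of cholesterol synthesis, was higher in WT cDC1 than in WT cDC2 (log2 fold change 1.82 ± 0.17, adjusted p = 0.013) and fell against WT cDC1 in +32 KO cDC2 (-2.07 ± 0.17, adjusted p = 0.0074) and Batf3 KO cDC2 (-1.73 ± 0.17, adjusted p = 0.012). Its list of 18 genes leaned to WT cDC1 (median 0.44, adjusted p = 1.4e-06, or 0.45 with an estimated correlation), fell in +32 KO cDC2 (median -0.44, adjusted p = 7.1e-05, or 0.51) and lay above WT cDC2 in Batf3 KO cDC2 (median 0.20, adjusted p = 5.2e-04, or 0.51). Glycolysis genes leaned lower in +32 KO cDC2 than in WT cDC1 (median -0.44, adjusted p = 0.017, or 0.64 with an estimated correlation). The list did not pass without +32 KO replicate 2 (median -0.12). Against WT cDC2 these genes were lower too (median -0.24, adjusted p = 0.034, or 0.64 with an estimated correlation). There the list did not pass without +32 KO replicate 2 (median -0.003) or WT cDC2 replicate 1 (-0.14). Between WT cDC1 and WT cDC2 they did not differ (median 0.10, adjusted p = 0.37). The lactate transporter gene Slc16a3 rose in Batf3 KO cDC2 against WT cDC1 (log2 fold change 1.41).

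Among genes of other programs, Gadd45b rose against WT cDC1 in +32 KO cDC2 (log2 fold change 4.11) and Batf3 KO cDC2 (4.27), while its list of immediate early and stress genes did not pass with all arrays (adjusted p = 0.49 and 0.083). Its median in +32 KO cDC2 was 0.19 with all arrays and 0.19 without replicate 2, which leaves 1 array in that group. The retinoid gene Dhrs3 was higher in WT cDC2 than in WT cDC1 (-2.04) and rose in +32 KO cDC2 (1.98) and Batf3 KO cDC2 (1.93), without a shift of the retinoid and Notch targets (adjusted p = 0.18 and 0.16). Apoptosis regulators leaned higher in Batf3 KO cDC2 than in WT cDC1 (median 0.40, adjusted p = 0.034, or 0.45 with an estimated correlation). The lean stayed without WT cDC1 replicate 1 (median 0.30) or Batf3 KO replicate 1 (0.42), but the list then did not pass the test.

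Genes set apart in both Batf3 KO arrays by at least 0.25 log2 units from all others lay near Batf3 more often than elsewhere: 6 of the 281 measured genes nearest to it on its chromosome, against 70 of 19637 others (odds ratio 6.1, Fisher's exact p = 7.2e-04, adjusted p = 0.0029 over 4 groups). Ifi202b (gap 1.68 log2 units) and Kcnj10 (0.91) had the widest gaps among them, and the other 3 groups had no such excess at this gap (odds ratios 0.89 to 2.81); at a gap of 0.5, 2 of 11 genes set apart in Batf3 KO cDC2 lay near Batf3 (Fisher's exact p = 0.010) and 1 of 1 in +32 KO cDC2 did (p = 0.014). The values at 0.25 are consistent with alleles of another strain carried along with the targeted locus, though few genes bear on it and the wider gap does not set Batf3 KO cDC2 apart, and Ifi202b is known to be expressed in some inbred strains and silent in others. Loss of Batf3 itself could not be told apart from that: signed by the difference between WT cDC1 and WT cDC2, the 6 genes had a median of -0.068, with 3 of 6 in the direction such a loss predicts. No genotype of the mice beyond the targeted gene was available.

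A hypothesis was tested from the spread of Irf8 among cDC2 arrays, namely that Irf8 follows the DC maturation genes, whose mean was higher on replicate 2 than on replicate 1 in all 4 groups. Over the 6 cDC2 arrays, Irf8 correlated with the DC maturation mean at r = 0.923 (rank correlation 0.829). With arrays swapped only within their groups, the exact permutation p was 0.25 for r and 0.38 for ranks, and the 8 possible orders allow none below 0.125. A permutation over all 6 arrays ignores the groups and the shared difference between replicates, so its p-value (exact permutation p = 0.0097 for r, 0.058 for ranks) is not read as support. The correlation was 0.459 without replicates 2 of +32 KO cDC2 and Batf3 KO cDC2, so it rests on these arrays and the data cannot tell. Cell cycle genes ran against the DC maturation mean at r = -0.555 without passing (exact permutation p within groups = 0.38), and at -0.025 without the same 2 arrays.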
